A study of Mus musculus with 6 samples.

How the data were processed

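Total RNA of brain microglia from 3 control and 3 CKO samples was extracted with TRIzol and turned into biotinylated cDNA with an Affymetrix whole-transcript kit, per the labels' protocols. How the microglia were isolated is not given in the sources used here. The deposited table holds one log2 expression value per probe set and array, which the authors made with RMA (robust multi-array average: background correction, normalization and probe summary), per the submitters' processing notes; its version, its settings and the annotation build are not given in the sources used here. The log2 scale was read from the values, which ran from 2.93 to 19.93. RMA commonly ends with arrays of equal distribution, yet the 6 arrays differed in their interquartile range, and the step that left this difference is not given in the sources used here.

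The table had 22206 probe sets, 19572 of them naming 1 gene symbol in the platform annotation, 0 naming several and 2634 unnamed here. All 19572 matched a mouse gene table (assembly GRCm38.p6) by Entrez gene number, and 0 symbols changed. The mouse table was used only for names and for which genes lie in the MHC region. These gave 19505 genes, 55 of them with more than 1 probe set, for which the probe set with the highest mean over the 6 arrays stood for the gene. Values of 254 probe sets were identical to those of another on all arrays, so near-identical genes can share probes. No probe set was marked as a control by its identifier, and all columns of sample values were assigned. No measure of signal over background was used here; genes close to the lowest values have an uncertain level, and values close to the top may be saturated.

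Groups came from the sample labels. Values were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes without trend, CKO minus control, no covariate), with two-sided tests and Benjamini-Hochberg adjustment over all 22206 probe sets at 0.05. Named genes at an unadjusted p under 0.05 and 1.5-fold were counted as a description without control of false discoveries. Gene lists were tested with limma's camera (preset inter-gene correlation of 0.01) on 1 probe set per gene, with adjustment over all 35 lists of at least 5 measured genes. Camera compares a list with all other genes. With the correlation estimated from the data, 0 of the 26 list calls held, and the lowest adjusted p was 0.111. The fry test, which asks whether the genes of a list move on balance one way, called 16 lists, all lower. "Adjusted over the list alone" means Benjamini-Hochberg adjustment of the limma p-values of that list's genes. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1 and was not used.

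The 19 gene lists covered homeostatic and disease-associated microglia, inflammatory cytokines and enzymes, chemokines, MHC class II with costimulation, MHC class I antigen processing, type I interferon and interferon-gamma responses, GM-CSF receptor and STAT5 signalling, complement and Fc receptors, lysosome and phagocytosis, NADPH oxidase and oxidative stress, alternative activation, cholesterol, glycolysis, oxidative phosphorylation, cell cycle, Toll-like receptor and NF-kB signalling, and the immediate early response. The 16 marker lists covered monocytes, border-associated macrophages, neutrophils, dendritic cells, T, NK and B cells, mast cells with eosinophils, erythroid cells, astrocytes, oligodendrocytes and their precursors, neurons, endothelial cells, pericytes with fibroblasts, and ependymal with choroid plexus cells. They held 656 measured genes, 37 of them in more than 1 list; some listed genes are not reported here. The lists, tests, thresholds, most other settings and the rule for naming genes were fixed before the data were examined.

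The rule named up to 12 genes per direction with adjusted p under 0.05 and groups that did not overlap, by fold change. As fewer passed, genes with the smallest p followed until 6 were named per direction. Gene models without a proper name and receptor, microRNA and antigen-receptor segment families were passed over unless listed. Further genes were the up to 4 members of a described list with the smallest p (6 for a called list), up to 2 members that went against their list at p under 0.05, and Csf2, Csf2ra, Csf2rb, Csf2rb2, Tmem119, P2ry12, Aif1, Itgam and Ptprc, of which Csf2rb2 was not analysed here. Slc1a2 comes from the astrocyte list.

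Other settings tried were quantile normalization, median centring, filters on the dimmest 20% and 50% of probe sets, a trended robust fit, array weights, the replicate number as a block, each array left out, the mean of a gene's probe sets, an adjusted p of 0.1, a 2-fold threshold, a plain two-group test, the estimated correlation, fry, ranks, and lists without shared genes. Cyclic loess, the neural marker covariate and the omission of array pairs were chosen after seeing the data.

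The fit was tested on simulated data drawn from the means and residual spreads of all 22206 probe sets, in 5 runs with 200 genes changed. It called 1.2% of genes changed by 1 log2 unit, 51.6% at 2, 79.6% at 3 and 91.6% at 4, with 22 false among 582 calls and 0 of the wrong sign. On simulated values of 19505 genes with independent errors, camera found 40 of 40 shifted lists and made 4 false calls; correlated genes, which real data hold, were not simulated. Names and figures were handled with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.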

Results

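Brain microglia, the resident macrophages of the brain, were profiled at the height of experimental autoimmune encephalomyelitis (EAE), a mouse model of multiple sclerosis induced here with recombinant myelin oligodendrocyte glycoprotein. RNA from 3 control samples and 3 conditional knock-out (CKO) samples was hybridised, 1 array per sample, all from female C57BL/6 mice. The labels give the knock-out as one in B cells, and the series title ties it to B cells that express GM-CSF, a cytokine that activates myeloid cells; the deleted gene itself is not given in the sources used here. The comparison asks how microglia differ during EAE when this B cell population is altered. Each array gave 22206 log2 values, and with 3 arrays per group the number of arrays limits the precision. The labels do not say that the replicates are separate animals, so the p-values measure only the spread between these samples, which may be technical.

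The arrays also differed within the groups. Median values were 7.16, 7.20 and 7.13 on control replicates 1, 2 and 3, and 7.18, 7.34 and 7.34 on CKO replicates 1, 2 and 3. The interquartile range was 3.08 and 3.11 on CKO replicates 2 and 3, against 3.66 to 4.0 on the other arrays, so the narrow range occurs only in CKO. CKO replicate 1 correlated across probe sets at 0.975 with control replicate 2, and at 0.932 and 0.937 with CKO replicates 2 and 3; probe sets are not independent replicates. Astrocyte markers such as Slc1a2, a glutamate transporter, were highest on CKO replicate 1 (16.92) and control replicate 2 (15.02). These features are set beside the gene groups they move with.

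Microglial isolates of CKO mice had lower values of antigen presentation and interferon-response genes than those of controls. These were shifts of whole lists, which held with a preset correlation between genes and lost their calls with an estimated one (adjusted p = 0.111 to 0.123 with an estimated correlation, T cell, NK cell and monocyte lists included). H2-Ab1, a chain of MHC class II that presents antigen to CD4 T cells, stood at 16.39 ± 0.59 (SD, n = 3) in controls and 12.12 ± 0.71 in CKO (adjusted p = 0.058). Markers of T cells, NK cells and blood monocytes were lower in the same isolates, with Cd3e, a chain of the T cell receptor complex, at 11.53 ± 1.68 and 7.36 ± 0.87 (adjusted p = 0.121). Neither gene passed over all genes. Two-sided limma tests over all probe sets called Anpep and C4a, both lower in CKO, and no probe set higher. P2ry12, a marker of resting microglia, was at 19.14 ± 0.33 and 19.69 ± 0.04, near the top of the scale. Of 23 such markers, 18 were higher and 5 lower in CKO, and 0 passed over all genes. Their group difference rested on CKO replicate 1 and control replicate 3.

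**Figure D1:**
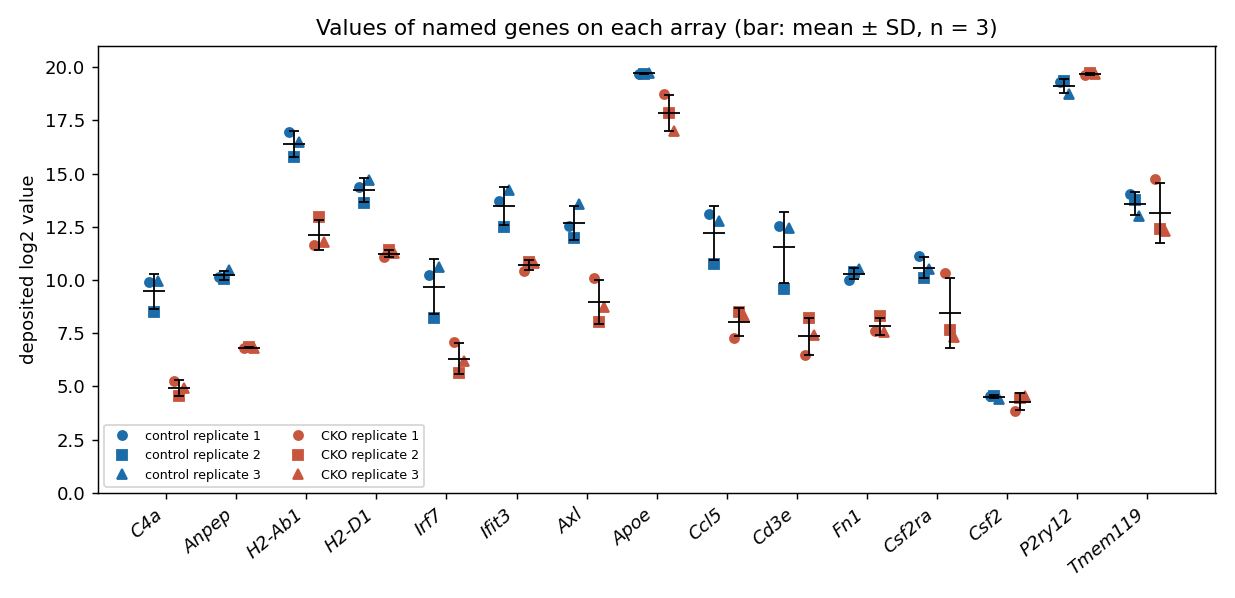
Deposited log2 values of 15 named genes on each of the 6 arrays, controls in blue and CKO in red, with a symbol per replicate number and a black bar for the mean ± SD of 3 arrays. C4a, Anpep and H2-Ab1 lie lower on all 3 CKO arrays than on any control array, while Csf2ra and Tmem119 split within the CKO group.

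Csf2, which encodes GM-CSF, was at 4.51 ± 0.07 in controls and 4.29 ± 0.39 in CKO, close to the lowest values of the arrays (log2 fold change -0.22, SE 0.29, adjusted p = 0.798). The samples are labelled as microglia and the knock-out is in B cells, so this value does not check the labels. Csf2ra, the ligand-binding chain of the GM-CSF receptor, was at 10.59 ± 0.51 in controls, and at 10.32, 7.64 and 7.33 on CKO replicates 1, 2 and 3 (adjusted p = 0.378). Csf2rb, the signalling chain, was at 10.59 ± 0.30 and 10.06 ± 0.21 (adjusted p = 0.561). B cell marker genes were not called as a list (median log2 fold change -0.22, camera adjusted p = 0.06). This depended on the setting: the list was called lower under quantile normalization (adjusted p = 0.0248) and cyclic loess (0.0149), and without control replicate 1 (0.0153), CKO replicate 2 (0.0154) or CKO replicate 3 (0.0243). Of its 19 measured members, 2 passed adjusted over the list alone and 0 over all genes: Jchain, which joins immunoglobulin polymers in plasma cells, fell by 4.98, and Cd22, a B cell lectin, fell by 2.22 on the log2 scale. Jchain was at 5.14, 8.8 and 5.98 on CKO replicates 1, 2 and 3.

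Anpep, an aminopeptidase on the surface of myeloid cells, fell by 3.40 on the log2 scale (SE 0.26, limma adjusted p = 0.0148), from 10.22 ± 0.20 to 6.82 ± 0.03. C4a fell by 4.55 (SE 0.43, adjusted p = 0.044), from 9.46 ± 0.82 to 4.92 ± 0.37. Its call ended under quantile normalization (adjusted p = 0.0575, change -4.53) and with the dimmest 20% of probe sets left out (0.0533). C4a and its near-identical paralog C4b, which encodes complement component C4, can share probes, so the 2 cannot be fully separated; C4b differed by -4.32 (adjusted p = 0.0891). Below these, the genes with the smallest p missed the threshold: H2-Ab1 (log2 fold change -4.27, adjusted p = 0.058), H2-D1, an MHC class I heavy chain (-2.99), H2-Eb1 of MHC class II (-4.68) and Slfn5, an interferon-inducible Schlafen gene (-3.18), these last 3 at adjusted p = 0.0745. Genes with higher CKO values also missed it. Cyp2j6, a fatty acid epoxygenase, differed by 1.41 (adjusted p = 0.109) and Lyve1, a hyaluronan receptor of lymphatic vessels and border macrophages, by 1.33 (0.145). Prok2, a secreted prokineticin, differed by 1.22, Tll1, a tolloid protease, by 1.35, Rapgef5, an activator of Rap GTPases, by 1.12, and Ptprd, a receptor phosphatase, by 1.32, at adjusted p from 0.15 to 0.197.

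Over all probe sets, 2 passed at adjusted p under 0.05 and 44 at 0.1, all of them lower in CKO. An unadjusted p under 0.05 was reached by 788 higher and 1409 lower probe sets, with 1110 expected by chance in all. Of 19505 named genes, 1900 reached that p and 1.5-fold, 1258 of them lower (66.2%). That balance depended on the arrays: 2736 were higher and 2740 lower without CKO replicate 1, and 1216 higher and 927 lower (43.3%) without CKO replicates 2 and 3. That last setting holds 1 CKO array, the one with the highest neural markers, and takes its spread from the controls alone, here and below. The groups did not overlap for 14.4% of probe sets, against 10% by chance. Anpep and C4a lost their calls when control replicate 1, control replicate 3, CKO replicate 2 or CKO replicate 3 was left out, which left 0, 0, 1 and 0 probe sets called. Without control replicate 2 the count was 125. Without CKO replicate 1 it was 2209, with 1113 higher and 1096 lower. That CKO group is only the 2 narrow-range arrays, so group and value range cannot be told apart in that setting, here and below. The 1900 genes became 1102 without control replicate 1, 1057 without control replicate 3, 5476 without CKO replicate 1 and 1135 without CKO replicate 3.

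**Figure D2:**
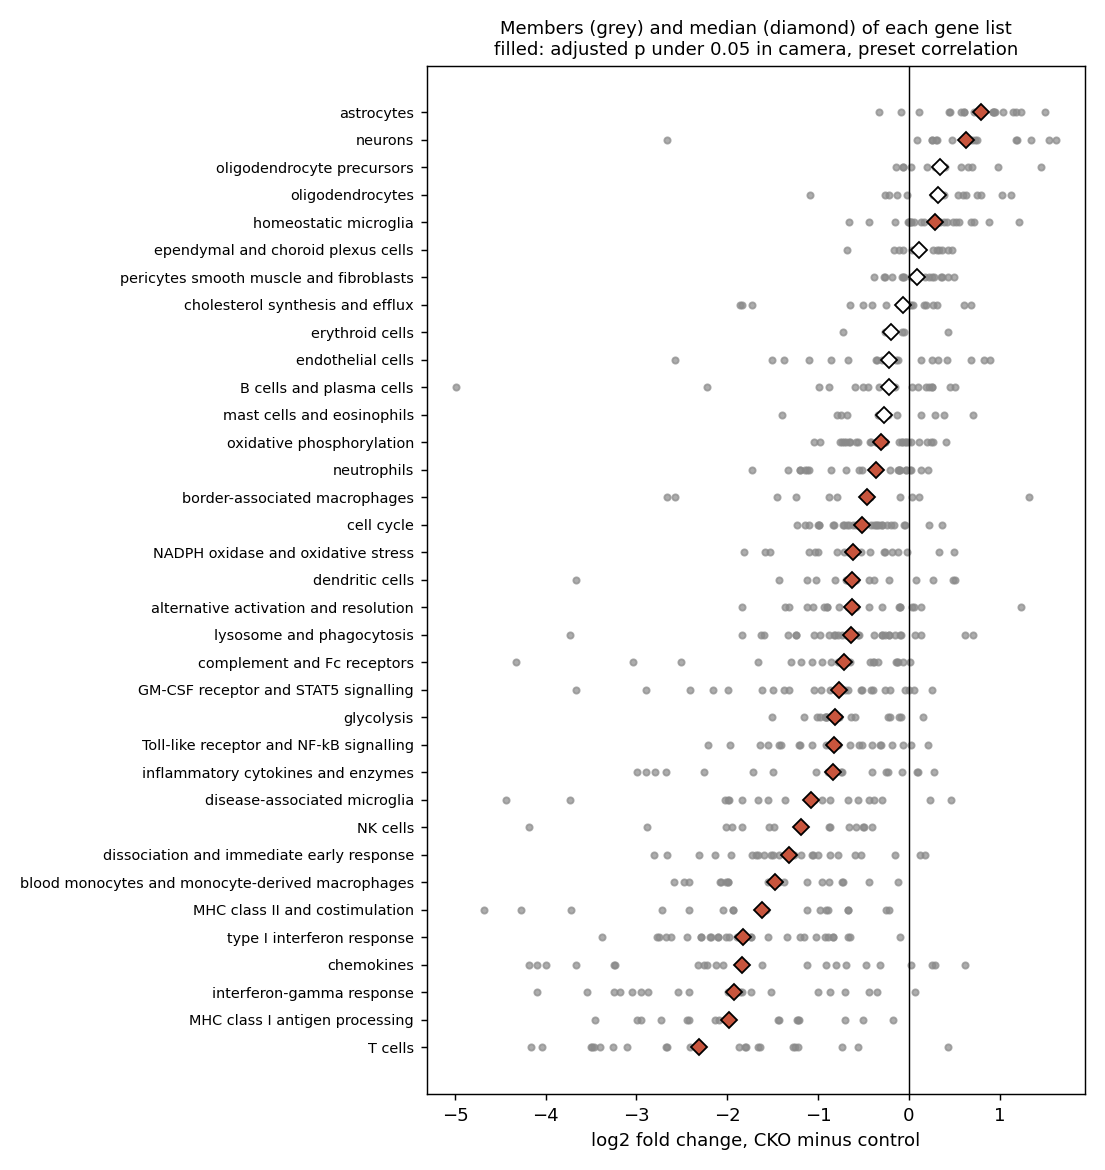
Log2 fold change of CKO against control for each measured member (grey points) of 35 gene and cell type marker lists, with the median of each list as a diamond, filled where camera with a preset correlation gave an adjusted p under 0.05. T cell markers and the MHC and interferon lists have medians between -2.31 and -1.61, and the astrocyte median is 0.79.

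Antigen presentation genes fell together. All 18 measured genes of MHC class II and costimulation were lower in CKO, with a median log2 fold change of -1.61, and 13 passed adjusted over the list alone, 0 over all genes. H2-Eb1, H2-Ab1 and H2-Aa, chains of the class II molecule, differed by -4.68, -4.27 and -3.72, and H2-DMa, which helps load peptides, by -2.72. All 17 MHC class I genes were lower, with a median of -1.98, and 15 passed adjusted over the list alone, 0 over all genes. The heavy chains H2-D1 and H2-K1 differed by -2.99 and -2.73, and Tap1, a peptide transporter, by -2.95. Both lists were called by camera (adjusted p = 3.7e-18 and 5.81e-20); adjusted p = 0.111 and 0.112 with an estimated correlation. Control replicate 2 lay closer to the CKO arrays than the other controls did, with a mean deviation of 0.41 for class II (0.99 and 1.33 on the others) and 0.23 for class I (1.08 and 1.43). T cell, NK cell and monocyte markers differed by medians of -2.31, -1.19 and -1.47 beside these genes.

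The type I interferon response fell (camera adjusted p = 1.57e-26; adjusted p = 0.112 with an estimated correlation). All 31 of its measured genes were lower, with a median of -1.83, and 24 passed adjusted over the list alone, 0 over all genes. Ifit3 and Ifit3b, antiviral effector genes, differed by -2.77 and -2.68, Irf7, a transcription factor that amplifies interferon production, by -3.38, and Oasl2 by -2.62. Of 22 interferon-gamma response genes, 21 were lower, with a median of -1.92 (camera adjusted p = 2.24e-18; adjusted p = 0.112 with an estimated correlation), and 17 passed adjusted over the list alone, 0 over all genes. Irf1 and the class II transactivator Ciita differed by -2.0 and -1.94, the GTPase gene Igtp by -2.55, and Cxcl9, a chemokine for T cells, by -4.10. Control replicate 2 lay between the groups for these genes: its mean deviation from the 6 arrays was 0.06 for type I interferon and -0.09 for interferon-gamma genes, against 1.08 to 1.82 for the other controls and -1.05 to -0.69 on the CKO arrays. Astrocyte markers deviated by 1.06 on control replicate 2, and T cell markers differed between groups by a median of -2.31 beside these genes.

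Markers of infiltrating leukocytes were lower in CKO. Of 23 T cell markers, 22 were lower, with a median of -2.31 (camera adjusted p = 5.16e-22; adjusted p = 0.112 with an estimated correlation), and 20 passed adjusted over the list alone, 0 over all genes. Cd3d, Cd3g and Cd3e of the T cell receptor complex differed by -3.10, -4.04 and -4.17, and Cd8a, the cytotoxic co-receptor, by -3.49. All 14 NK cell markers were lower, with a median of -1.19 (camera adjusted p = 4e-10; adjusted p = 0.123 with an estimated correlation), and 8 passed adjusted over the list alone, 0 over all genes; the receptor gene Klrc1 differed by -2.02 and the granule protease gene Gzma by -1.95. All 20 markers of blood monocytes and their macrophages were lower, with a median of -1.47 (camera adjusted p = 6.69e-18; adjusted p = 0.111 with an estimated correlation), and 12 passed adjusted over the list alone, 0 over all genes. Fn1 (fibronectin) and Tgfbi, both of the extracellular matrix, differed by -2.48 and -2.42, and Lyz2 (lysozyme) by -2.01. Ptprc, which encodes the leukocyte antigen CD45, was at 15.48 ± 0.20 and 14.19 ± 0.76 (adjusted p = 0.324). Control replicate 2 lay between the groups here too: its mean deviation was 0.13 for T cells (1.63 and 1.62 on the other controls), -0.09 for NK cells (1.11 and 1.15) and 0.20 for monocytes (1.05 and 0.999).

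Other leukocyte markers were less uniform. Border-associated macrophage markers had a median of -0.46 (camera adjusted p = 0.000195; adjusted p = 0.111 with an estimated correlation), and of 14 genes 4 lower and 1 higher passed adjusted over the list alone, 0 over all genes. Ms4a7 fell by 2.58 and Siglec1, a sialic acid receptor, fell by 1.45, whereas Lyve1 rose by 1.33, each adjusted over the list alone. Dendritic cell markers had a median of -0.62 (camera adjusted p = 0.00102; adjusted p = 0.237 with an estimated correlation), 3 of 16 passing adjusted over the list alone and 0 over all genes: Ccl22, Dpp4 and Itgae at -3.66, -1.43 and -1.03. That call was lost without CKO replicate 1 (adjusted p = 0.129) and with the dimmest 50% of probe sets left out (0.28). The dendritic median was -0.39 without control replicate 1 and -0.23 without CKO replicate 1. Neutrophil markers had a median of -0.36 (camera adjusted p = 0.000224; adjusted p = 0.237 with an estimated correlation), and only Il1r2, a decoy receptor for interleukin-1, passed adjusted over the list alone (-1.73), with 0 of 23 over all genes; the call was lost with CKO replicate 1 alone against the controls (adjusted p = 0.0719). The neutrophil median was -0.20 without CKO replicate 2 and -0.55 without control replicate 3.

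Chemokine and cytokine genes were lower. Of 22 chemokine genes 18 were lower, with a median of -1.83 (camera adjusted p = 4.32e-11; adjusted p = 0.111 with an estimated correlation), and 11 passed adjusted over the list alone, 0 over all genes. Ccl5, a chemoattractant of T cells that T and NK cells also express, differed by -4.19, Ccl8 by -3.23 and Cxcl13, which attracts B cells, by -3.99. Of 19 inflammatory cytokine and enzyme genes 16 were lower, with a median of -0.83 (camera adjusted p = 9.34e-08; adjusted p = 0.112 with an estimated correlation), and 7 passed adjusted over the list alone, 0 over all genes. Tnf differed by -2.80 and Il1rn, the interleukin-1 receptor antagonist, by -2.89. Genes of Toll-like receptor and NF-kB signalling had a median of -0.83 (camera adjusted p = 4e-10; adjusted p = 0.111 with an estimated correlation), with 9 of 22 passing adjusted over the list alone and 0 over all genes; Nfkbiz differed by -2.21 and Tlr2, a receptor for bacterial lipopeptides, by -1.55. Chemokine genes deviated by 0.32 on control replicate 2, against 0.92 and 1.36 on the other controls, and T cell, NK cell and monocyte markers differed by medians of -2.31, -1.19 and -1.47 beside these groups.

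Immediate early genes, which respond to stimulation and also to tissue dissociation, had a median of -1.32 (camera adjusted p = 3.99e-14; adjusted p = 0.121 with an estimated correlation), and 15 of 25 passed adjusted over the list alone, 0 over all genes. The AP-1 genes Fos and Junb differed by -2.81 and -2.31, and Ier2 by -1.68. The list mean deviated by 0.05 on control replicate 1 and by 0.84 and 1.06 on control replicates 2 and 3. Beside this group, T cell, NK cell and monocyte markers differed by medians of -2.31, -1.19 and -1.47.

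The disease-associated microglia programme, induced where myelin or other debris is taken up, fell (median -1.08, camera adjusted p = 1.04e-12; adjusted p = 0.111 with an estimated correlation). Of 20 genes 18 were lower, and 12 passed adjusted over the list alone, 0 over all genes. Axl, a receptor for the removal of apoptotic cells, differed by -3.73, Itgax (CD11c) by -2.0, Lgals3 (galectin-3) by -1.66 and Igf1 by -1.36, while Apoe, the lipid carrier, went from 19.71 ± 0.04, near the top of the scale, to 17.87 ± 0.85. GM-CSF receptor and STAT5 signalling genes had a median of -0.77 (camera adjusted p = 1.01e-10; adjusted p = 0.111 with an estimated correlation), and 9 of 26 passed adjusted over the list alone, 0 over all genes. Pim1, a kinase gene induced by STAT5, differed by -2.41 and Jak2, the kinase bound to the receptor, by -1.04; Itgax, Ccl22 and Il1rn of this list also belong to other lists, as do 10 of its genes in all. Monocyte markers differed by a median of -1.47 beside both groups.

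Complement and Fc receptor genes had a median of -0.72 (camera adjusted p = 1.53e-09; adjusted p = 0.111 with an estimated correlation), with 8 of 20 passing adjusted over the list alone and 0 over all genes. Fcgr4, an activating receptor for IgG, differed by -2.51, and the complement genes Cfp and Cfb by -1.66 and -3.04. Lysosome and phagocytosis genes had a median of -0.64 (camera adjusted p = 1.82e-08; adjusted p = 0.111 with an estimated correlation), and 5 of 31 passed adjusted over the list alone, 0 over all genes. Msr1, a scavenger receptor, differed by -1.84 and Npc2, a cholesterol carrier of the lysosome, by -1.33, whereas Pros1, a ligand of Axl family receptors, differed by 0.70. Alternative activation genes had a median of -0.63 (camera adjusted p = 4.87e-05, and adjusted p = 0.111 with an estimated correlation). Of these 20 genes 3 passed adjusted over the list alone and 0 over all genes. Chil3 differed by -1.12 and Vegfa by 1.23. Chil3 is also in the monocyte list, and 10 of the 20 genes belong to another list. Monocyte markers differed by a median of -1.47 beside these groups, and complement and Fc receptor genes deviated by 0.18 on control replicate 2, against 0.66 and 0.68 on the other controls. Lysosome and phagocytosis genes deviated by -0.15 on CKO replicate 1, and by -0.41 and -0.49 on the narrow-range CKO replicates 2 and 3. On the controls they deviated by 0.25 to 0.43.

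**Figure D3:**
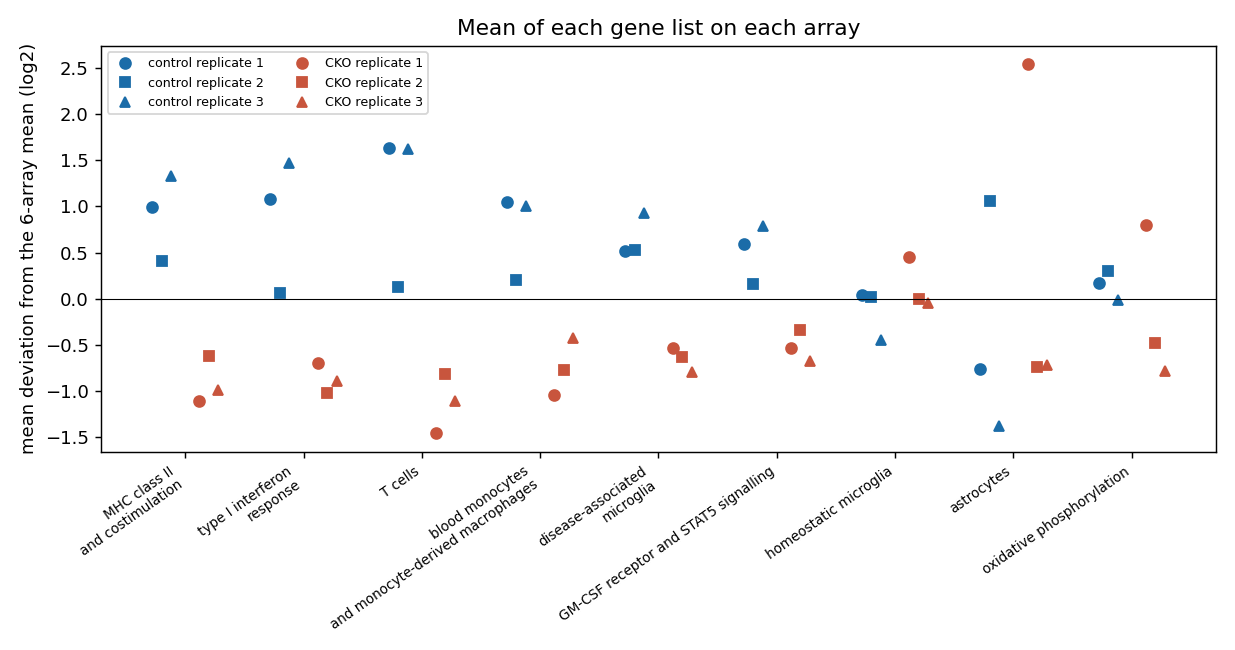
Mean deviation of 9 gene lists from the 6-array mean on the log2 scale, for each control array in blue and each CKO array in red, with a symbol per replicate number. MHC class II, interferon and T cell lists are lower on all 3 CKO arrays than on the controls, astrocyte markers peak on CKO replicate 1 (2.54) and control replicate 2 (1.06), and oxidative phosphorylation genes on CKO replicate 1 (0.80).

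Genes of resting microglia were slightly higher in CKO (median 0.29, camera adjusted p = 0.0142; adjusted p = 0.509 with an estimated correlation), and 0 of 23 passed adjusted over the list alone or over all genes. Mean deviations of the list were 0.04, 0.02 and -0.45 on control replicates 1, 2 and 3, and 0.45, -0.01 and -0.05 on CKO replicates 1, 2 and 3. The group difference thus rested on CKO replicate 1 and control replicate 3. Fcrls and Gpr34, both microglial surface receptors, differed by 1.21 and 0.89, and Il10ra, an interleukin-10 receptor chain, by -0.66. Tmem119, a microglial surface marker, was at 14.77, 12.41 and 12.29 on CKO replicates 1, 2 and 3, against 13.60 ± 0.53 in controls. Aif1, which encodes IBA1, was at 15.21 ± 0.39 and 14.85 ± 0.26, and Itgam (CD11b) at 16.94 ± 0.24 and 16.96 ± 0.24. The call was lost without CKO replicate 1 (adjusted p = 0.59) or control replicate 3 (0.196), with array weights (0.412) and with the mean neural marker value as a covariate (0.314), and without control replicate 2 and CKO replicate 1 (0.352). Astrocyte markers (median 0.79, adjusted p = 0.0247; adjusted p = 0.65 with an estimated correlation) and neuron markers (median 0.63, adjusted p = 0.0145; adjusted p = 0.509 with an estimated correlation) were called higher, with 0 astrocyte genes passing adjusted over the list alone and 1 neuron gene, Thy1, which T cells also carry, passing at -2.66; neither list had a gene past the threshold over all genes. Without CKO replicate 1 the astrocyte median was -0.29 and the neuron median 0.08, and neither was called (adjusted p = 0.223 and 0.841). Without control replicate 2 the medians were 1.40 and 1.07. Both calls were also lost without control replicate 1 (adjusted p = 0.103 and 0.0706) or control replicate 3 (0.426 and 0.156), with array weights (0.694 and 0.151) and with the covariate (0.312 and 0.548). Without control replicate 2 and CKO replicate 1, the arrays with the highest neural markers, the astrocyte call was lost (adjusted p = 0.128) and the neuron call was kept (0.0338).

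Several metabolic lists had their lowest means on the narrow-range arrays, CKO replicates 2 and 3. Glycolysis genes had a median of -0.81 (camera adjusted p = 1.72e-06; adjusted p = 0.28 with an estimated correlation), with Pfkfb3, a regulator of the pathway, at -1.15 and the glucose transporter Slc2a1 at -1.51. The glycolysis median was -0.475 without CKO replicate 3. NADPH oxidase and oxidative stress genes had a median of -0.61 (camera adjusted p = 1.23e-05; adjusted p = 0.205 with an estimated correlation), with the oxidase subunits Cyba and Cybb at -1.53 and -1.58. Cell cycle genes had a median of -0.52 (camera adjusted p = 4.62e-06; adjusted p = 0.299 with an estimated correlation), with the S-phase regulator E2f1 at -1.14. The cell cycle median was -0.84 without control replicate 2 and -0.32 without control replicate 3. Oxidative phosphorylation genes had a median of -0.31 (camera adjusted p = 0.0247; adjusted p = 0.66 with an estimated correlation), with Cox5a at 10.59, 8.9 and 8.58 on CKO replicates 1, 2 and 3. Without CKO replicate 1 that median was -0.75. Adjusted over the list alone, 4 of 20 NADPH oxidase genes passed and 0 of 18, 30 and 28 in the glycolysis, cell cycle and oxidative phosphorylation lists, and none of the 4 lists had a gene past the threshold over all genes. The list means deviated by 0.24, 0.15, 0.0023 and 0.80 on CKO replicate 1 for glycolysis, NADPH oxidase, cell cycle and oxidative phosphorylation genes, against -0.42, -0.53, -0.42 and -0.48 on CKO replicate 2 and -0.86, -0.56, -0.36 and -0.78 on CKO replicate 3. With CKO replicate 1 alone against the controls, the first 3 calls were lost (adjusted p = 0.606, 0.518 and 0.0835) and oxidative phosphorylation was called higher (median 0.64, adjusted p = 1.28e-07), which for 1 array describes that array only. The oxidative phosphorylation list also lost its call without control replicate 2 (adjusted p = 0.116), CKO replicate 2 (0.311) or CKO replicate 3 (0.972), under quantile normalization (0.305) or cyclic loess (0.487), and with the dimmest 20% (0.0719) or 50% (0.539) of probe sets left out.

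The remaining lists were not called by camera on the deposited values, and several were called in other settings. Cholesterol synthesis and efflux genes had a median of -0.06 (adjusted p = 0.074), with 3 of 20 passing adjusted over the list alone and 0 over all genes: Nceh1, which releases stored cholesterol, at -1.86, the lipid droplet gene Plin2 at -1.72, and Apoe at -1.84. That list was called lower with array weights (adjusted p = 0.0248), with the covariate (0.0247), without CKO replicate 1 (0.00988) and without control replicate 2 and CKO replicate 1 (0.0271). Endothelial markers had a median of -0.22 (adjusted p = 0.06), with 2 of 18 passing adjusted over the list alone and 0 over all genes; they were called lower by fry (adjusted p = 0.0229), under quantile normalization (0.025) and cyclic loess (0.0184), and without CKO replicate 2 (0.0385) or CKO replicate 3 (0.0482). Medians were -0.27 for mast cell and eosinophil markers (adjusted p = 0.098), -0.20 for erythroid cells (0.525), 0.33 for oligodendrocytes (0.111), 0.34 for their precursors (0.0666), 0.09 for pericytes, smooth muscle and fibroblasts (0.525), and 0.12 for ependymal and choroid plexus cells (0.329). The oligodendrocyte and precursor lists were called higher without control replicate 2 (adjusted p = 0.000647 and 0.0077) or CKO replicate 2 (0.0161 for both), and the precursor list with the dimmest 20% left out (0.0216). The oligodendrocyte list was also called without CKO replicate 3 (0.0226), and the mast cell list, lower, without control replicate 3 (0.0348). With CKO replicate 1 alone against the controls, oligodendrocyte (adjusted p = 0.00014) and precursor (0.0129) markers were called higher and B cell markers lower (0.0109), which for 1 array describes that array only. In these 6 lists 0 genes passed adjusted over the list alone and 0 over all genes.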

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

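Cyclic loess, the neural marker covariate and the omission of array pairs were tests chosen after the results were seen, and without CKO replicates 2 and 3 the CKO group is 1 array. The 2 called probe sets became 1 under quantile normalization, 1 with the dimmest 20% and 1 with the dimmest 50% of probe sets left out, 4 with a trended robust fit, 1694 with array weights and 44 at an adjusted p of 0.1. Leaving out single arrays gave 0 to 2209, with 125 without control replicate 2 and 2209 without CKO replicate 1; the count was 2516 without control replicate 2 and CKO replicate 1, 0 without CKO replicates 2 and 3, and 440 with the covariate. Over all settings that gave a value, Anpep differed by -3.52 to -3.28 (adjusted p = 0.00139 to 0.245) and C4a by -5.2 to -4.19 (adjusted p = 0.000427 to 0.425). C4a also missed the threshold under quantile normalization (0.0575) and with the dimmest 20% left out (0.0533), and it was among the dimmest 50%; both genes missed it under the replicate block (0.110 and 0.101) and without CKO replicates 2 and 3 (0.0968 and 0.233). The 1900 genes were 1054 at 2-fold, 1224 with a plain two-group test, 5472 with array weights, 5653 without control replicate 2 and CKO replicate 1, 3863 with the covariate, and 1057 to 5476 with single arrays left out. Fewer arrays or other weights changed the spread estimate, and the cause of each move was not tested. Where CKO replicate 1 was left out, only the narrow-range CKO arrays remained, so group and value range cannot be told apart there. The array weights gave CKO replicate 1 the lowest weight (0.258). The share of lower genes was 66.2%, and 81.4% after centring each array on its median, which moved the median of all genes from 0.05 to -0.07; with the dimmest 50% left out it was 84.2%. It was 50% without CKO replicate 1, 49.2% without control replicate 2 and CKO replicate 1, 49.7% with the covariate, 51.5% with array weights and 43.3% without CKO replicates 2 and 3, so the excess of lower genes depends on the setting. The 26 list calls became 0 with an estimated correlation and 16 with fry. In the other 20 settings with the preset correlation, 23 to 29 lists were called, and 17 of the 23 lower lists were called lower in each. The replicate block left 0 probe sets, 1885 genes and 26 lists; same-numbered samples correlated at -0.01, -0.23 and 0.25 in their deviations from the group means, so the numbers were not taken as pairs. Of 168 named genes, 161 kept their direction throughout. Most were named for a small p in these same data. Where the groups do not overlap, leaving out arrays cannot turn the direction, so this count is largely fixed by the choice of genes. Without CKO replicates 2 and 3, Cox5a turned to 0.25, Sdhd to 0.01, Ndufa2 to 0.18, Sdhb to 0.25 and Tmem119 to 1.17. Csf2 turned to 0.03 without control replicate 2 and CKO replicate 1, and ranged from -0.35 to 0.0017 with single arrays left out. Itgam, at 0.02, turned to -0.11 with median centring, -0.17 with array weights, -0.23 without control replicate 2 and CKO replicate 1, and -0.02 with the covariate, and ranged from -0.12 to 0.14 with single arrays left out; none of these reversals concerned a called gene.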

Other observations

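Gene families sharing a symbol stem, 318 with at least 8 measured members, were tested with camera after the lists had been seen; 21 were called lower and 15 higher in CKO, and none was called with an estimated correlation (adjusted p = 0.859 for each family named here). All 13 members of the Ifi family, interferon-inducible genes that include DNA sensors, were lower, with a median log2 fold change of -2.25 (camera adjusted p = 1.63e-12). Ifi211 differed by -2.97, Ifi213 by -3.73 and Ifi204 by -2.51, none past the threshold over all genes. Of 8 Gimap genes, GTPases of lymphocytes, 7 were lower (median -1.16, camera adjusted p = 2.46e-05), with Gimap3 at -2.62. Of 9 Slfn genes 7 were lower (median -1.28, camera adjusted p = 0.000266), with Slfn2 at -1.62. These 3 families kept a lower median under quantile normalization, median centring and cyclic loess, and T cell, NK cell and monocyte markers differed by medians of -2.31, -1.19 and -1.47 beside them.

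Ribosomal protein genes of the Rpl stem were lower (median -1.07, 38 of 40 members, camera adjusted p = 1.64e-19), and so they were under quantile normalization (-0.82), median centring (-1.20) and cyclic loess (-0.84). Over all 60 ribosomal protein genes the medians were 14.58, 14.2 and 14.52 on control replicates 1, 2 and 3, and 13.94, 12.67 and 12.9 on CKO replicates 1, 2 and 3. On the narrow-range CKO replicates 2 and 3, 88.3% had their lowest values. A share of 6.7% holds by chance for 2 arrays named beforehand. These 2 were picked for their range, and these genes are far brighter than the median probe set, so 6.7% is no fair reference. Olfactory (Olfr) and vomeronasal (Vmn) receptor genes, used in sensory neurons of the nose, had median log2 fold changes of 0.47 and 0.60; together their median was 5.34, 6.45 and 6.39 on CKO replicates 1, 2 and 3, against 5.52 to 5.65 on the controls.

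All tests of explanations below were chosen after the results were seen. Lower MHC and interferon-response genes in CKO were weighed against the narrow value range of CKO replicates 2 and 3, a linked MHC haplotype and cell composition. On CKO replicates 2 and 3 the 86 genes of the MHC and interferon lists differed from controls by a median of -1.865, and 80.5% of it was left relative to the 200 genes nearest each in control level (-1.50, quartiles -2.08 and -0.999), which argues against the narrow range as the whole cause; CKO replicate 1, with a wide range, lay below all 3 controls for 89.5% of them and for 30.3% of all genes. Interferon-response genes outside the MHC region had a median of -1.89, which argues against a linked haplotype as the whole cause. Within the region 96 genes had a median of -0.04, but members of the lists and H2, C4, Tap and Psmb genes were left out of these. A haplotype share in the changes of the MHC and C4 genes themselves therefore stays open. Fewer infiltrating T cells, NK cells and monocytes could account for part of the difference and cannot be told apart from a response of the microglia: the medians of the MHC lists and of the markers of these cells differed by 0.01, and no gate that would remove these cells is named in the labels. Of these markers 1 of T cells, 1 of NK cells and 3 of monocytes belong to another list. The effect of the B cell knock-out on microglia itself stays open and untested.

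The narrow value range of CKO replicates 2 and 3 was weighed next. Quantile normalization gives all arrays the same distribution, so it removes the narrow range by construction and cannot test array scaling as its cause. It left 56.5% of the shift of 1412 olfactory and vomeronasal receptor genes on these arrays. Array scaling is thus argued against only as the whole cause of the shift of these receptor genes. These genes were higher by 0.74 (median) on the lower of these arrays than on any other, and CKO replicate 1 lay at -0.31 relative to the highest control. Both values restate which arrays have a narrow range and decide nothing. CKO replicate 1 has the same label and an interquartile range of 4.0, so the B cell genotype alone does not account for the narrow range. A compressed signal scale and a part played by the genotype cannot be told apart and stay open.

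High neural markers in control replicate 2 and CKO replicate 1 were weighed last. These arrays were the highest for 61.5% of 65 astrocyte, oligodendrocyte, precursor and neuron markers, which restates how they were picked, so RNA from brain cells other than microglia stays open. These arrays are a control and a CKO array, so the B cell genotype alone does not account for the pattern. The neural marker mean of CKO replicates 2 and 3 lay at -0.989 or lower relative to control replicate 2. That value too restates how the arrays were picked and decides nothing. On control replicate 2 and CKO replicate 1, Slc1a2 of astrocytes was at 15.02 and 16.92, and Mbp, a major myelin protein of oligodendrocytes, at 18.11 and 19.37, against at most 12.90 and 15.60 on the other arrays, and no gate that would remove these cells is named in the labels.

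The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 2 called probe sets and the highest other split 0, so 1 split reached the real count. It gave 1900 genes at unadjusted p under 0.05 and 1.5-fold, and the highest other split gave 2938; 3 splits, the real one included, reached 1900, and both others set CKO replicates 2 and 3 with one control array against the rest, a structure of the samples. It gave 26 list calls and the highest other split 24, with 1 split reaching the real count.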
